A study of Homo sapiens with 12 samples.

How the data were processed

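RNA was measured in human dermal lymphatic endothelial cells, primary cells from the lining of lymphatic vessels of the skin. The cells carried a lentiviral shRNA against Nogo-B (shNogo-B) or, as control, against GFP (shGFP), and were grown without TGF-β2 or with TGF-β2 at 10 ng/mL for 3 days. Each of the 4 groups held 3 libraries, grouped by their titles, and the labels name a single batch. Libraries were made from total RNA with a SMARTer mRNA kit. Whether the protocol kept the strand was not given in the sources used here.

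The authors deposited 1 gene-level TPM table (transcript abundance scaled to a fixed total per library), keyed by gene symbol. Per the submitters' processing notes, kallisto, DESeq2 and GRCh38 (hg38) were used, with no versions. The annotation release and the way transcripts were summed to genes were not given in the sources used here. The table held 15858 gene lines, and its columns summed to between 958948 and 966265, so genes outside it held the remainder. TPM keeps no read depth, so depth is unknown and no counting interval was computed. The values are not counts, so no count model was run.

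Before testing, 3 lines without a gene name, at most 0.0022% of a library, and 1 exact duplicate line were left out. A further 53 symbols stood on 107 lines, which were summed per symbol, and this left 15784 genes. XIST and Y-linked genes were left out of all results. Genes with a TPM of at least 1 in at least 3 of the 12 libraries were tested, 14111 in all. Values were analysed as log2(TPM + 1). Fold changes are on this scale, which understates the change of genes with low TPM.

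The test was limma with a mean-variance trend, a single fit of 4 group means over all 12 libraries. It gave 5 comparisons: TGF-β2 in shGFP cells, TGF-β2 in shNogo-B cells, knockdown without TGF-β2, knockdown with TGF-β2, and their interaction, which is the TGF-β2 response in shNogo-B cells minus that in shGFP cells. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. These choices, the alternatives other than those named below as later, the gene lists and the rule for named genes were fixed before the data were examined.

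The 29 gene lists covered endothelial and lymphatic identity, the endothelial-to-mesenchymal transition (EndMT), matrix, TGF-β and BMP signalling, reticulons, stress, metabolism, proliferation, immune genes and markers of other cell types. For each list, called members were counted over all genes tested and with p adjusted over the list alone. Lists with at least 3 tested members were tested against all other genes with camera (limma), with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Camera p-values were adjusted by Benjamini-Hochberg over the lists of a comparison. The hepatocyte, intestinal epithelial and epithelial marker lists, added later, were adjusted among themselves alone. Adjustment over so few lists is milder, so their adjusted p cannot be set beside those of the lists fixed beforehand. The text names RTN4, then the 10 called genes with the largest change in each direction (5 for TGF-β2 in shNogo-B cells and the interaction), given groups that did not overlap and a mean TPM of at least 2. It also names up to 4 members with the smallest p from each list with a called member or a camera call. Symbols that are only clone or database identifiers were passed over. Some genes that meet the rule are not reported here.

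Some results were added after the data were seen. These are both main effects (knockdown averaged over treatments and TGF-β2 averaged over shRNAs), the count of TGF-β2 genes that knockdown moved further in the TGF-β2 direction, lists of hepatocyte, intestinal epithelial and epithelial markers, the mean hepatocyte marker level as a covariate, removal of LINC01766, the most abundant gene, and the reticulon list without RTN4. The alternatives fixed earlier were pseudocounts of 0.1 and 0.5, no filter, a mean TPM of at least 5, median-of-ratios scaling, a fit to the libraries of the compared groups alone, limma without trend, array weights, a replicate block, a log2 fold change of at least 1, an estimated inter-gene correlation, and each library left out in turn.

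The method was tested on simulated data in which 200 of 14111 genes were changed, over 20 draws. Noise was normal and independent between genes, with the variances fitted to these data. Unfolded protein response genes were also raised by 0.3, and their calls were not counted as false. For knockdown with TGF-β2, 32.8%, 76.6% and 94.8% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and 4.4% of calls were false. For the interaction, the recovered shares were 15.4%, 52.9% and 89.4%, with 5.1% false calls. These shares hold under that model and do not measure false calls in data whose genes vary together.

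Gene positions are from GENCODE release 29 on GRCh38. Of the 226 named genes, 65 have exons that overlap those of a gene on the opposite strand. How reads of the shared stretches were assigned was not checked, and strand information was not given. Reads shared between near-identical genes (AKR1C2 and AKR1C1, metallothioneins, HLA genes) were divided by the authors' quantification, and this was not checked. The gene value of RTN4 sums all its isoforms, so Nogo-B was not measured apart from the others. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.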

Results

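Levels below are mean TPM ± SD over the 3 libraries of a group (n = 3), and changes are log2 fold changes with their standard error (SE). The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The knockdown was made with shRNA labelled shNogo-B alone, so effects of lower RTN4 were not separated from effects of the shRNA on other transcripts. Members named to complete a count of 5 or fewer were chosen after their values were seen. Whether calls are kept without a library was followed only for genes that the naming rule chose. Tallies cover all of these, and genes given as losing a call are those named in the text.

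RTN4 encodes the reticulon proteins, Nogo-B among them, that shape tubular endoplasmic reticulum. It lies on chromosome 2 of GRCh38 at 54972187 to 55112621. Without TGF-β2, RTN4 stood at 412 ± 24.5 TPM in shGFP cells and at 84.1 ± 1.05 TPM in shNogo-B cells, which is 20.4% of the shGFP level (log2 fold change −2.28, SE 0.06, limma Benjamini-Hochberg adjusted p = 2.41e-11). With TGF-β2, it stood at 404 ± 5.41 TPM and 80.0 ± 4.17 TPM, or 19.8% (−2.32, SE 0.06, adjusted p = 1.85e-11). TGF-β2 itself was not called for RTN4 in shGFP cells (−0.03, adjusted p = 0.912) or in shNogo-B cells (−0.07, adjusted p = 0.657).

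In shGFP cells, TGF-β2 raised MMP2, a gelatinase (chromosome 16, 55389700 to 55506691), from 26.9 ± 0.4 to 81.0 ± 0.834 TPM (1.56, SE 0.07). IGFBP5, a secreted binding protein of insulin-like growth factors (chromosome 2, 216672105 to 216695525), rose from 2.59 ± 0.247 to 13.1 ± 0.593 TPM (1.97, SE 0.12), and GDF6, a ligand of the BMP family (chromosome 8, 96142330 to 96160792), from 5.42 ± 0.674 to 23.3 ± 1.38 TPM (1.92, SE 0.13). TAGLN, an actin-binding protein of smooth muscle (chromosome 11, 117199321 to 117204782), rose from 245 ± 9.04 to 516 ± 7.997 TPM (1.07, SE 0.07), and FN1, which encodes fibronectin, from 3792 ± 64.2 to 6131 ± 130 TPM (0.69, SE 0.03). RELN, a secreted glycoprotein of lymphatic endothelium (chromosome 7, 103471784 to 103989516), fell from 108 ± 0.858 to 58.4 ± 4.16 TPM (−0.88, SE 0.10). INHBB, an activin subunit (chromosome 2, 120346143 to 120351808), fell from 8.92 ± 0.4 to 2.48 ± 0.687 TPM (−1.53, SE 0.18). Adjusted p for these 7 genes in limma (Benjamini-Hochberg) ran from 4.71e-08 for MMP2 to 0.000262 for INHBB.

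Of 19 tested mesenchymal and smooth muscle markers of EndMT, 8 rose and VIM fell, and 9 rose and 1 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.92e-12). POSTN, a matrix protein, rose from 195 ± 10.2 to 360 ± 14.1 TPM, and FSTL3 from 34.0 ± 0.891 to 58.2 ± 2.47 TPM. Of 27 extracellular matrix and crosslinking genes, 13 rose and MFAP2 fell, with 14 up and 2 down adjusted over the list alone (camera adjusted p = 2.41e-14). Among these were COL5A1, a fibrillar collagen, from 43.4 ± 4.05 to 92.0 ± 1.40 TPM, and SPARC from 2291 ± 73.2 to 3413 ± 54.3 TPM. Of 28 SMAD2/3 target genes, 9 rose and TIMP3 fell, with 14 up and 1 down adjusted over the list alone (camera adjusted p = 1.03e-11). LTBP2, a latent TGF-β binding protein of the matrix, rose from 143 ± 12.5 to 312 ± 14.7 TPM. With an estimated correlation, the adjusted p of these 3 lists was 0.00480, 0.00696 and 0.0279, and no other list fixed beforehand kept its call.

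Of 15 lymphatic identity genes tested, 10 had a negative and 5 a positive change, with a median of −0.08. RELN, MMRN1 and SOX18 fell, with 4 down adjusted over the list alone (camera adjusted p = 0.00525; adjusted p = 0.119 with an estimated correlation). MMRN1, a secreted multimerin, fell from 536 ± 22.5 to 318 ± 4.14 TPM. In the proliferation list, BIRC5, CCNB1, TOP2A and UBE2C fell among 29 tested, with 8 down adjusted over the list alone (camera adjusted p = 1.51e-09; adjusted p = 0.0898 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitosis, fell from 69.4 ± 2.31 to 51.0 ± 3.86 TPM. Of 17 matrix proteases and inhibitors, 3 rose, MMP10 and MMP2 among them, and TIMP3 fell, with 5 up and 1 down adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.105 with an estimated correlation). Of 21 YAP and SRF target genes, 6 rose and NT5E fell, with 9 up and 1 down adjusted over the list alone (camera adjusted p = 1.39e-05; adjusted p = 0.119 with an estimated correlation). ANKRD1, a mechanosensitive cofactor, rose from 827 ± 30.5 to 1217 ± 49.7 TPM.

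Among Notch and vascular growth factor genes, APLN, ESM1 and NOTCH4 rose and ANGPT2 fell of 25, with 8 up and 1 down adjusted over the list alone (camera adjusted p = 5.37e-05; adjusted p = 0.119 with an estimated correlation). In the unfolded protein response list, CALR and PDIA4 rose of 22, with 6 up adjusted over the list alone (camera adjusted p = 5.86e-06; adjusted p = 0.105 with an estimated correlation). Camera also called glycolysis and hypoxia up (adjusted p = 0.00870; PFKP and SLC2A1 rose), cholesterol synthesis up (adjusted p = 0.0280; none called), fibroblast markers up (adjusted p = 0.0267; COL1A2 rose), blood endothelial markers up (adjusted p = 0.00608; CCN2 and NOTCH4 rose) and antigen presentation down (adjusted p = 0.00870; HLA-E fell). With an estimated correlation these gave adjusted p = 0.254, 0.271, 0.154, 0.154 and 0.154. Of the lists without a camera call, those of endothelial identity (adjusted p = 0.246) and of TGF-β ligands, receptors and SMADs (adjusted p = 0.0812) still held called members. ENG, ESAM and MMRN2 rose and CLDN5 and FLI1 fell in the former, and ENG, INHBA and TGFB2 rose and INHBB fell in the latter. CLDN5, the main claudin of endothelial tight junctions, fell from 150 ± 5.31 to 83.8 ± 2.06 TPM, and TGFB2 rose from 27.8 ± 1.31 to 50.2 ± 2.93 TPM. Camera adjusted p was 0.246 for EMT transcription factors, where SNAI1 rose, 0.581 for BMP and SMAD1/5 targets, where ENG rose, and 0.436 for sphingolipid genes, where PLPP3 fell. It was 0.581 for p53 targets, where IGFBP7 rose and PLK2 fell, and the list's median of −0.03 and mean of 0.02 differed in sign. It was 0.104 for junction genes, with RHOB up and CLDN5 down, and 0.267 for heat shock and oxidative stress genes, with MT1X and MT2A up. No member was called among reticulons (adjusted p = 0.224), inflammatory genes (0.954, median −0.04 and mean 0.03), interferon-stimulated genes (0.246), mural (0.246) and leukocyte (0.0812) markers or mitochondrially encoded genes (0.177). Only 2 keratinocyte markers were tested, neither was called in any comparison, and camera was not run on them.

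In limma, 362 genes were called for TGF-β2 in shGFP cells, 211 up and 151 down, and 36 changed at least 2-fold. The count was 234 without shGFP control replicate 1, 218 without replicate 2, 213 without shGFP TGF-β2 replicate 1 and 228 without replicate 3. It was 203 in limma without trend. Of the 64 called gene results that the rule named here, 48 kept their call without any single library. Of those named in the text, PLPP3, CALR, PDIA4, TOP2A, CCNB1, PLK2, HLA-E, RHOB and MT1X each lost it without at least one library, and none changed sign. The camera calls of the cholesterol and fibroblast lists were also lost without a library (highest adjusted p = 0.102 and 0.128).

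TGF-β2 in shNogo-B cells changed largely the same genes. POSTN (chromosome 13, 37562583 to 37598844) rose from 322 ± 10.8 to 734 ± 61.4 TPM (1.19, SE 0.06), MMP2 from 51.3 ± 3.64 to 143 ± 4.99 TPM (1.46, SE 0.07) and IGFBP5 from 4.61 ± 0.280 to 27.9 ± 0.976 TPM (2.37, SE 0.12). TGFBI, a matrix adaptor induced by TGF-β, rose from 116 ± 2.86 to 259 ± 2.46 TPM (1.16, SE 0.05). CLU, a secreted chaperone (chromosome 8, 27596917 to 27615031), fell from 747 ± 52.7 to 346 ± 21.9 TPM (−1.11, SE 0.06), RELN from 65.1 ± 3.70 to 33.0 ± 5.07 TPM (−0.97, SE 0.10) and INHBB from 7.35 ± 1.00 to 2.27 ± 0.345 TPM (−1.35, SE 0.18). HSPA5, the main chaperone of the endoplasmic reticulum (chromosome 9, 125234853 to 125241330), rose from 446 ± 13.6 to 706 ± 52.3 TPM (0.66, SE 0.06). Adjusted p in limma (Benjamini-Hochberg) ran from 4.18e-08 for TGFBI to 0.000864 for INHBB. Between the TGF-β2 responses of shGFP and shNogo-B cells, 127 genes rose in both, 92 fell in both and 0 were called in opposite directions. Independent lists of these sizes would share 2.86 and 1.79. Of the 362 genes called in shGFP cells, 354 had the same sign in shNogo-B cells. Across all tested genes, which are not independent replicates, the responses correlated at r = 0.319 (0.211 with the hepatocyte marker covariate, a fit that ties both responses to a shared coefficient and for which no simulated value was made).

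Of 22 unfolded protein response genes, 10 rose in shNogo-B cells, also when adjusted over the list alone (camera adjusted p = 5.24e-16; adjusted p = 0.0104 with an estimated correlation). HSP90B1, an endoplasmic reticulum chaperone, rose from 572 ± 13.9 to 841 ± 53.3 TPM, and CALR, a calcium-binding chaperone, from 1358 ± 41.1 to 1712 ± 14.3 TPM. Of 19 EndMT markers, 10 rose and VIM fell, the same counts as adjusted over the list alone (camera adjusted p = 2.08e-08; adjusted p = 0.00919 with an estimated correlation). Of 27 matrix genes, 12 rose and MFAP2 fell, with 14 up and 1 down adjusted over the list alone (camera adjusted p = 4.11e-14; adjusted p = 0.00919 with an estimated correlation). Of 28 SMAD2/3 targets, 7 rose and TIMP3 fell, with 11 up and 1 down adjusted over the list alone (camera adjusted p = 2.57e-12; adjusted p = 0.0176 with an estimated correlation). BIRC5, CCNB1, TYMS and UBE2C fell among 29 proliferation genes, with 19 down adjusted over the list alone (camera adjusted p = 1.55e-15; adjusted p = 0.0176 with an estimated correlation). Of 15 lymphatic genes, GJA4, MMRN1, RELN and SOX18 fell, with 2 up and 6 down adjusted over the list alone (camera adjusted p = 0.000351; adjusted p = 0.0745 with an estimated correlation). GJA4, a connexin of endothelium, fell from 739 ± 21.1 to 563 ± 19.8 TPM. Camera also called matrix proteases (adjusted p = 0.000241), YAP and SRF targets (0.000285), Notch genes (0.0128) and cholesterol synthesis (0.0148) up, and with an estimated correlation these gave adjusted p = 0.0911, 0.201, 0.327 and 0.301. Of 13 BMP and SMAD1/5 targets, ATOH8 and ID1 fell and ENG rose, with 1 up and 7 down adjusted over the list alone (camera adjusted p = 0.000168; adjusted p = 0.0786 with an estimated correlation).

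In limma, 358 genes were called for TGF-β2 in shNogo-B cells, 191 up and 167 down, and 40 changed at least 2-fold. The count was 204 without shNogo-B control replicate 2, 234 without replicate 3, 212 without shNogo-B TGF-β2 replicate 1 and 205 without replicate 3. It was 228 in limma without trend and 189 in a fit to the compared groups alone. With the mean level of hepatocyte markers as a covariate, chosen after the data were seen, it was 47. All 358 kept their sign with it, their median absolute change went from 0.51 to 0.47, and the median SE over genes rose from 0.16 to 0.25. Of the 66 called gene results that the rule named here, 45 kept their call without any single library and 28 with the covariate. CCNB1, UBE2C and ATOH8, named in the text, lost theirs without at least one library. The camera calls of the cholesterol and Notch lists were also lost without a library (highest adjusted p = 0.0847 and 0.104). Hepatocyte markers had a median change of −0.39 in this comparison (19 tested, 1 down, 12 down adjusted over the list alone; camera adjusted p = 1.39e-10; adjusted p = 0.0648 with an estimated correlation). The median was −0.22 without shNogo-B control replicate 1. Epithelial markers, listed after the data were seen, were lower here too (2 of 10 down; camera adjusted p = 0.00335; adjusted p = 0.0383 with an estimated correlation).

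**Figure D1:**
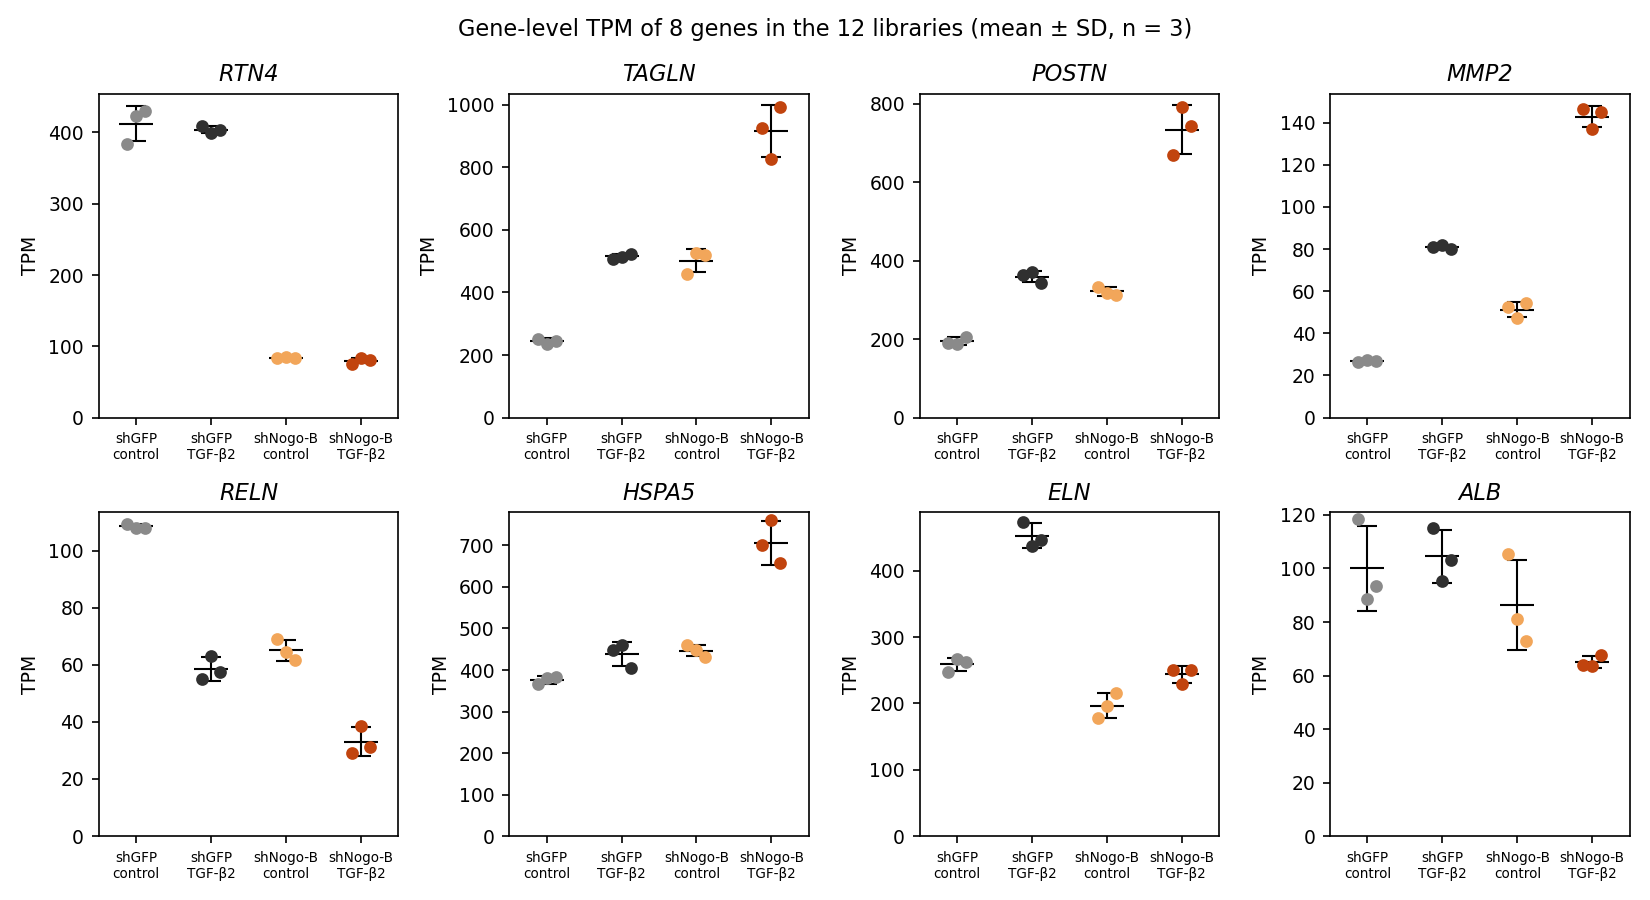
TPM of 8 genes in the 12 libraries of the 4 groups, with dots for libraries and bars for the group mean ± SD (n = 3). RTN4 lies lower in all shNogo-B libraries, TAGLN, POSTN and MMP2 lie highest with TGF-β2 and knockdown together, RELN lies lowest there, and ELN lies highest in shGFP cells with TGF-β2.

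Without TGF-β2, knockdown raised EDIL3, a secreted integrin ligand (chromosome 5, 83940554 to 84384793), from 2.34 ± 0.238 to 10.7 ± 1.10 TPM (1.80, SE 0.17). The noncoding transcript MEG3 (chromosome 14, 100779410 to 100861031) rose from 56.5 ± 5.36 to 128 ± 7.52 TPM (1.17, SE 0.08). Its neighbour MEG8 (100894770 to 101038859) rose from 3.47 ± 1.07 to 13.2 ± 2.69 TPM (1.67, SE 0.22). TAGLN rose from 245 ± 9.04 to 502 ± 36.5 TPM (1.03, SE 0.07), MMP2 from 26.9 ± 0.4 to 51.3 ± 3.64 TPM (0.90, SE 0.07) and POSTN from 195 ± 10.2 to 322 ± 10.8 TPM (0.72, SE 0.06). NUPR1, a stress-induced chromatin protein, fell from 24.1 ± 2.05 to 6.31 ± 1.02 TPM (−1.78, SE 0.23), IGFBP2 from 54.0 ± 5.31 to 24.9 ± 1.62 TPM (−1.08, SE 0.09) and RELN from 108 ± 0.858 to 65.1 ± 3.70 TPM (−0.73, SE 0.10). Adjusted p in limma (Benjamini-Hochberg) ran from 3.34e-06 for TAGLN to 0.00244 for MEG8. Exons of TAGLN, EDIL3, IGFBP5, MEG3, SPARC and ELN overlap genes on the opposite strand, and exons of MMP2 overlap a gene on its own strand.

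Of 19 EndMT markers, FSTL3, MYL9, POSTN, TAGLN and TPM1 rose and S100A4 fell, with 6 up and 2 down adjusted over the list alone (camera adjusted p = 0.000344; adjusted p = 0.156 with an estimated correlation). Of 17 matrix proteases and inhibitors, 2 rose, MMP2 among them, with 6 up and 1 down adjusted over the list alone (camera adjusted p = 3.62e-05; adjusted p = 0.156 with an estimated correlation). Of 28 SMAD2/3 targets, 3 rose, LTBP2 and TGFBI among them, with 9 up and 2 down adjusted over the list alone (camera adjusted p = 3.62e-05; adjusted p = 0.156 with an estimated correlation). COL5A1, SPARC and TGFBI rose and ELN fell among 27 matrix genes, with 8 up and 2 down adjusted over the list alone (camera adjusted p = 0.00562; adjusted p = 0.214 with an estimated correlation). COL5A1 went from 43.4 ± 4.05 to 72.3 ± 1.54 TPM. Of 13 mitochondrially encoded genes, MT-ND6 fell, with 6 down adjusted over the list alone (camera adjusted p = 2.01e-07; adjusted p = 0.156 with an estimated correlation). Proliferation genes had a positive median of 0.12 with 0 of 29 called, also adjusted over the list alone (camera adjusted p = 0.000680; adjusted p = 0.227 with an estimated correlation). Camera called 7 more lists, all lost with an estimated correlation (adjusted p = 0.156 to 0.393): EMT transcription factors, unfolded protein response, YAP and SRF targets and heat shock genes up, and reticulons, hypoxia and interferon-stimulated genes down. The reticulon list holds RTN4 itself, its one called member, and without RTN4 its adjusted p was 0.0285 (adjusted p = 0.274 with an estimated correlation).

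In limma, 106 genes were called for knockdown without TGF-β2, 63 up and 43 down, with 17 changed at least 2-fold. Leaving out shGFP control replicates 1, 2 and 3 gave 42, 31 and 53 genes, and leaving out shNogo-B control replicates 1, 2 and 3 gave 62, 48 and 39. The count was 29 in limma without trend, 36 in a fit to the compared groups alone and 40 with the hepatocyte marker covariate. All 106 kept their sign with the covariate, their median absolute change went from 0.47 to 0.46, and the median SE over genes rose from 0.16 to 0.18. Of the 45 called gene results that the rule named here, 22 kept their call without any single library and 28 with the covariate. Hepatocyte markers had a median change of −0.21 here with 0 of 19 called (camera adjusted p = 9.06e-05; adjusted p = 0.251 with an estimated correlation). These markers held 0.0773% of TPM in shNogo-B control replicate 1, like the shGFP libraries, against 0.0561% and 0.0556% in replicates 2 and 3, and without replicate 1 the median was −0.36 with 2 of 19 called. Epithelial markers were also called down here (1 of 10 down, camera adjusted p = 0.0469, adjusted p = 0.164 with an estimated correlation). ELN, which encodes elastin, lost its call when shGFP control replicate 2 or 3 or shNogo-B control replicate 1 or 2 was left out (log2 fold change −0.38, −0.39, −0.33 and −0.40). S100A4 and LTBP2 each lost their call without any one of 4 libraries, and FSTL3 and MT-ND6 without 1. The camera calls of the hypoxia, interferon-stimulated and heat shock lists were lost without a library (highest adjusted p = 0.0997, 0.265 and 0.0543), that of EMT transcription factors at a mean TPM of 5 or more (0.253), and those of the matrix and YAP and SRF lists in limma without trend (0.0542 and 0.0579).

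With TGF-β2, the comparison that the series design names, knockdown raised POSTN from 360 ± 14.1 to 734 ± 61.4 TPM (1.03, SE 0.06), IGFBP5 from 13.1 ± 0.593 to 27.9 ± 0.976 TPM (1.04, SE 0.12), TAGLN from 516 ± 7.997 to 915 ± 83.1 TPM (0.82, SE 0.07) and MMP2 from 81.0 ± 0.834 to 143 ± 4.99 TPM (0.81, SE 0.07). HSPA5 rose from 438 ± 28.3 to 706 ± 52.3 TPM (0.69, SE 0.06). ELN (chromosome 7, 74027789 to 74069907) fell from 452 ± 18.9 to 244 ± 12.4 TPM (−0.89, SE 0.07), S100A4, a calcium-binding protein, from 24.7 ± 4.81 to 8.34 ± 0.917 TPM (−1.45, SE 0.17) and RELN from 58.4 ± 4.16 to 33.0 ± 5.07 TPM (−0.81, SE 0.10). Adjusted p in limma (Benjamini-Hochberg) ran from 1.75e-06 for POSTN to 0.000547 for RELN and IGFBP5. EDIL3 and MEG3 rose with knockdown here too (1.79 and 1.24), and NUPR1 and IGFBP2 fell (−1.54 and −0.97). Between the knockdown effects without and with TGF-β2, 30 genes rose in both, 25 fell in both and 0 were called in opposite directions, where independent lists would share 0.286 and 0.149. Across all tested genes, which are not independent replicates, the knockdown effects correlated at r = 0.224 (0.454 with the hepatocyte marker covariate, a fit that ties both effects to a shared coefficient and for which no simulated value was made).

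Of 22 unfolded protein response genes, 9 rose with knockdown under TGF-β2, and 11 adjusted over the list alone (camera adjusted p = 8.46e-12; adjusted p = 0.0787 with an estimated correlation). HSP90B1 went from 607 ± 24.4 to 841 ± 53.3 TPM, CALR from 1337 ± 25.6 to 1712 ± 14.3 TPM and SDF2L1 from 72.4 ± 2.39 to 120 ± 3.72 TPM. Of 19 EndMT markers, 6 rose and S100A4 fell, with 10 up and 4 down adjusted over the list alone (camera adjusted p = 0.00455; adjusted p = 0.170 with an estimated correlation). Of 17 matrix proteases and inhibitors, 4 rose, MMP2, PLAT and PLAU among them, with 8 up and 3 down adjusted over the list alone (camera adjusted p = 0.000441; adjusted p = 0.170 with an estimated correlation). Of 28 SMAD2/3 targets, 3 rose, RGS4 and TGFBI among them, with 6 up and 2 down adjusted over the list alone (camera adjusted p = 0.000912; adjusted p = 0.217 with an estimated correlation). COL5A1, SPARC and TGFBI rose and ELN fell among 27 matrix genes, with 6 up and 3 down adjusted over the list alone (camera up, adjusted p = 0.0304; adjusted p = 0.324 with an estimated correlation), and the median of 0.09 and the mean of −0.03 differed in sign. BMPER fell among 13 BMP and SMAD1/5 targets, with 2 down adjusted over the list alone (camera adjusted p = 0.00192; adjusted p = 0.211 with an estimated correlation). ADM fell among 22 glycolysis and hypoxia genes, with 3 down adjusted over the list alone (camera adjusted p = 0.000912; adjusted p = 0.217 with an estimated correlation). Interferon-stimulated genes had a median of −0.17 with 0 of 26 called, also adjusted over the list alone (camera adjusted p = 0.000912; adjusted p = 0.170 with an estimated correlation). GJA4, MMRN1 and RELN fell among 15 lymphatic genes, with 1 up and 4 down adjusted over the list alone, and camera did not call the list (adjusted p = 0.0517).

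Transcripts of hepatocyte proteins, listed after some had been seen among the changed genes, moved with this comparison as well. All 19 tested were lower with knockdown under TGF-β2, 5 were called (18 adjusted over the list alone; 1 to 7 with a library left out), and their median change was −0.59 (camera adjusted p = 5.48e-25; adjusted p = 0.0156 with an estimated correlation). These camera values were adjusted over the lists added later alone, a milder adjustment than that of the lists fixed beforehand. ALB, which encodes albumin, stood at 105 ± 9.95 TPM in shGFP cells and 65.04 ± 2.40 TPM in shNogo-B cells with TGF-β2, and FGB, a fibrinogen chain, at 136 ± 9.86 and 92.7 ± 5.204 TPM. Together these markers made up between 0.0458% and 0.0773% of TPM in every library. Epithelial markers were not called by camera in this comparison (adjusted p = 0.0686, 1 of 10 down), nor were intestinal epithelial markers (adjusted p = 0.0686, 0 of 6 called). Epithelial markers were lower with TGF-β2 in shGFP cells, as in shNogo-B cells (2 of 10 down; camera adjusted p = 0.00223; adjusted p = 0.0235 with an estimated correlation).

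In limma, 113 genes were called for knockdown with TGF-β2, 64 up and 49 down, with 23 changed at least 2-fold. Leaving out shGFP TGF-β2 replicates 1, 2 and 3 gave 52, 64 and 55 genes, and leaving out shNogo-B TGF-β2 replicates 1 and 3 gave 58 and 50; limma without trend gave 57. With the hepatocyte marker covariate only RTN4, POSTN, MEG3, ELN and EPN3 were called, and 4 of these 5 were among the 113 called without it. The call of every other gene named for this comparison was lost with the covariate. All 113 kept their sign with it, their median absolute change went from 0.59 to 0.51, and the median SE over genes rose from 0.16 to 0.32. Of the 44 called gene results that the rule named here, 26 kept their call without any single library. SPARC, PLAT, BMPER, ADM and MMRN1, named in the text, lost theirs, and none changed sign. The camera calls of the BMP and matrix lists were also lost without a library (highest adjusted p = 0.0793 and 0.142), and with the covariate the EndMT, protease and unfolded protein response lists kept theirs. The matrix list lost its call in 10 of 23 alternatives, among them median-of-ratios scaling, limma without trend, array weights and the covariate.

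**Figure D2:**
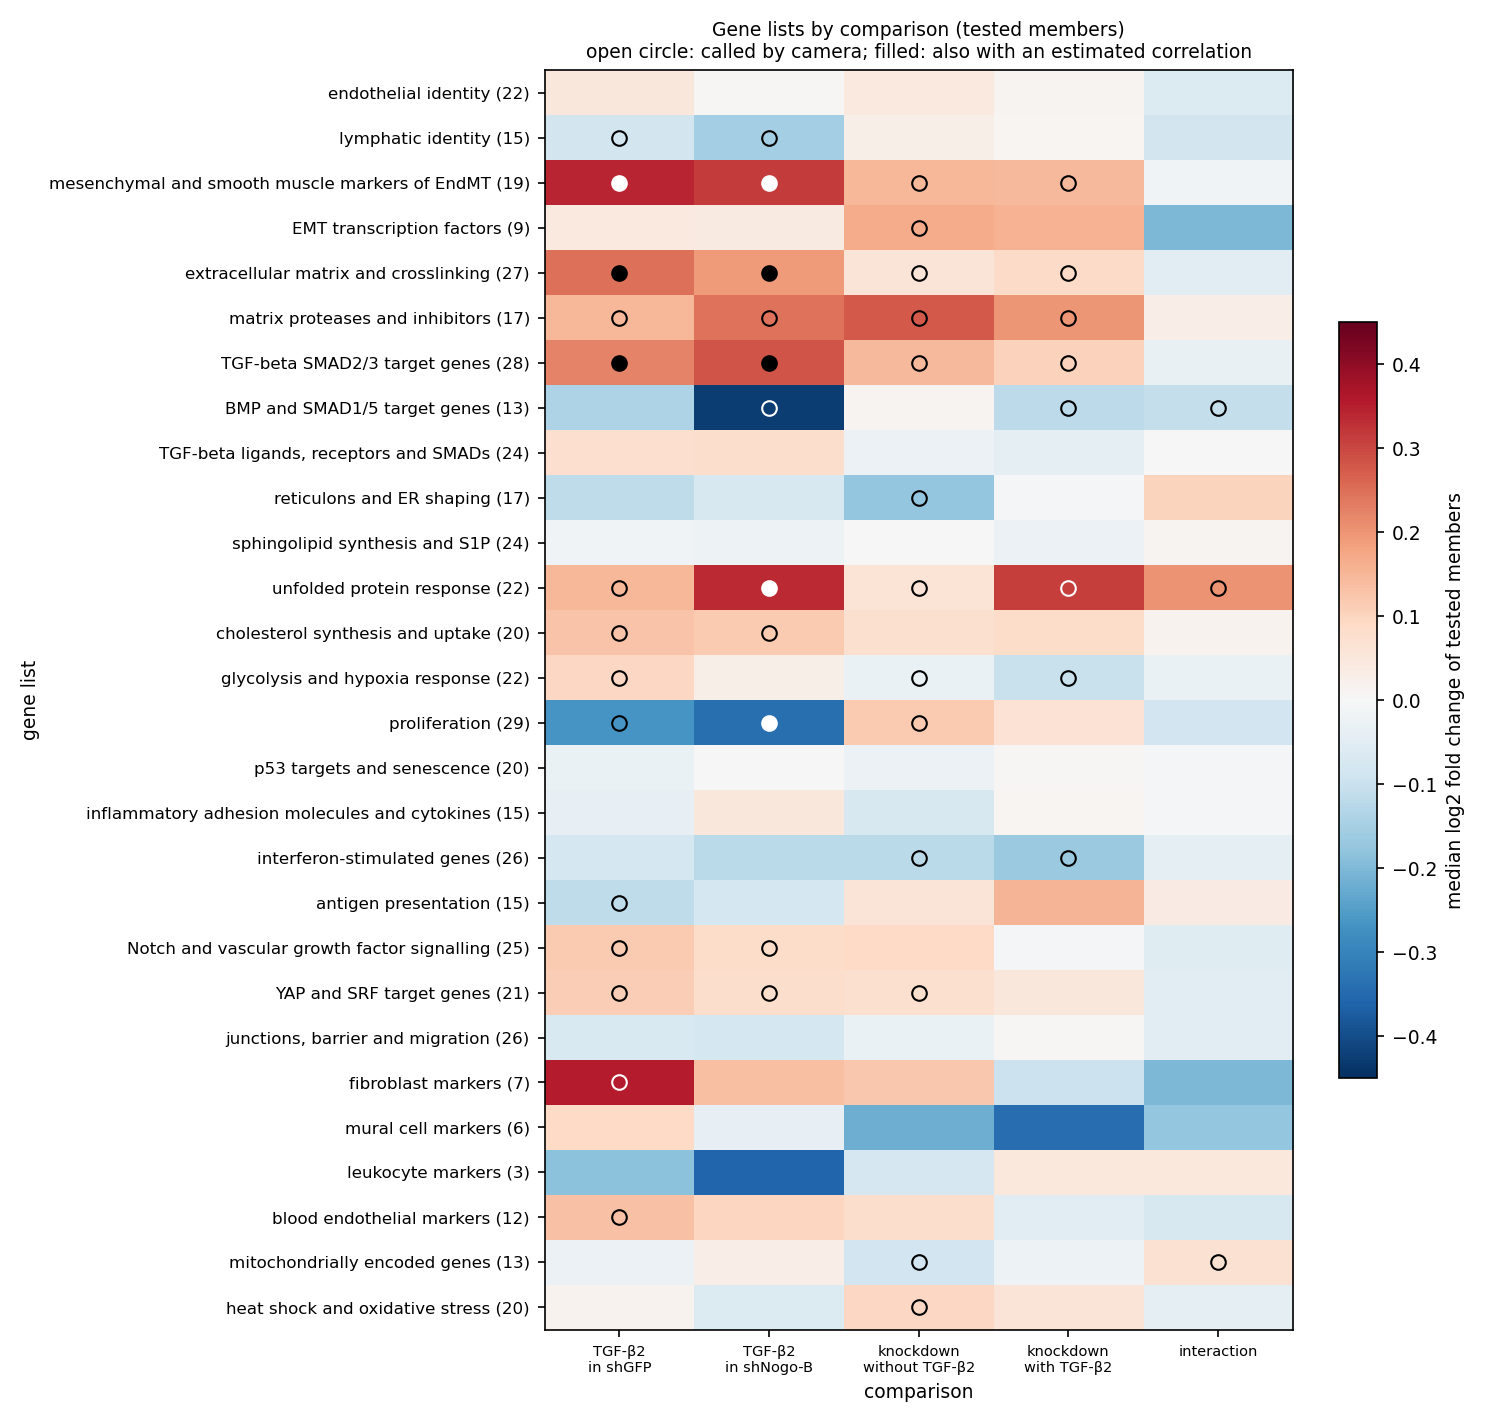
Median log2 fold change of the tested members of 28 gene lists (member number in brackets) in the 5 comparisons, as colour. Open circles mark lists that camera called at an adjusted p under 0.05 with the preset correlation, and filled circles those also called with an estimated correlation: 3 lists for TGF-β2 in shGFP cells, 5 in shNogo-B cells and 0 in the other comparisons.

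The direction of the knockdown effect was set against that of the TGF-β2 response. Of the 362 genes called for TGF-β2 in shGFP cells, 27 rose and 11 fell with both TGF-β2 and knockdown under TGF-β2, 38 in all. Independent lists would share 0.957 and 0.524. Of all 362, 250 had the same sign for knockdown with TGF-β2. Their median knockdown change in the TGF-β2 direction, over all 362, was 0.09, against 0.49 for TGF-β2 itself. TAGLN, POSTN, MMP2, IGFBP5, COL5A1, TGFBI and SPARC were among the genes that rose with both, and RELN, CLU and MMRN1 among those that fell. ELN and CIDECP1, a pseudogene, rose with TGF-β2 and fell with knockdown, and 0 genes did the reverse. CIDECP1 was listed at 0 in all shGFP control and shNogo-B TGF-β2 libraries. The shGFP TGF-β2 libraries enter both comparisons, which by itself pushes genes toward opposite directions. In 100 simulations of unchanged groups the correlation across genes averaged −0.5001, and the measured one was −0.265. Real effects of either kind also move the correlation toward 0, so this gap alone does not show a shared direction. The covariance, which unrelated effects leave unchanged on average, was −0.0187, above the simulated range of −0.0284 to −0.0231. The same count without those shared libraries, of TGF-β2 in shNogo-B cells against knockdown without TGF-β2, which share the shNogo-B controls instead, was 31 up in both, 15 down in both and 2 opposite, ELN and UQCC5. For this pair the correlation across genes was −0.236 against a simulated mean of −0.499. The covariance was −0.0159 against a simulated range of −0.0281 to −0.0226. Genes in these simulations were drawn independently. Genes that vary together within a library would widen both ranges, so a covariance outside them does not show a shared direction. The calls of SPARC, MMRN1 and CIDECP1 for knockdown with TGF-β2, and those of ELN and UQCC5 in this second count, were lost without at least one library.

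The count of 38 was chosen after the data were seen. It was 24 without shGFP control replicate 2, 18, 21 and 20 without shGFP TGF-β2 replicates 1, 2 and 3, and 23 and 21 without shNogo-B TGF-β2 replicates 1 and 3. With the hepatocyte marker covariate, POSTN alone was called in both. All 38 kept their sign there, their median change in the TGF-β2 direction went from 0.54 to 0.49, and their median SE rose from 0.07 to 0.14.

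**Figure D3:**
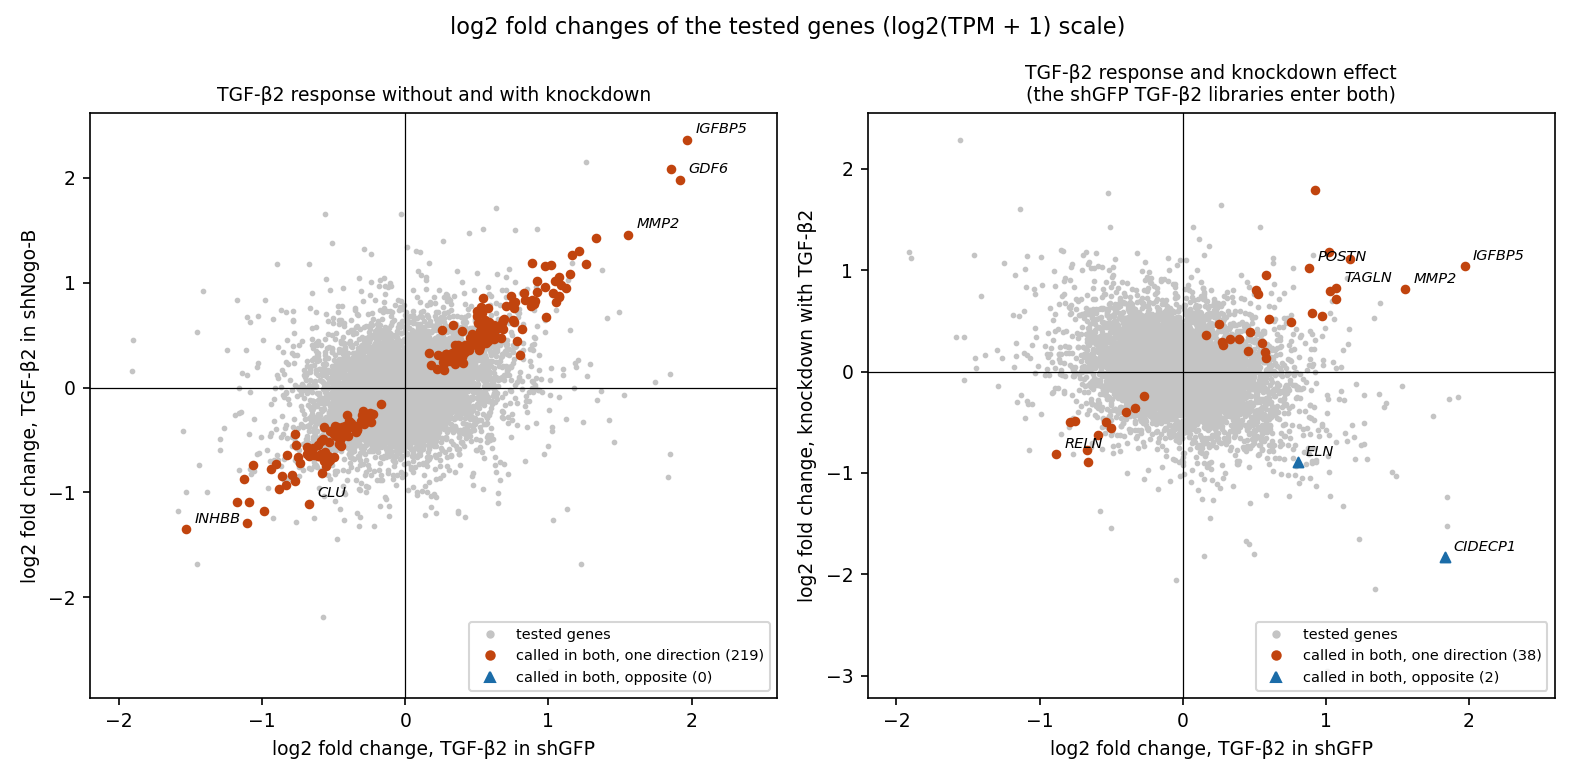
Log2 fold changes of the tested genes, RTN4 left out: the TGF-β2 response of shNogo-B cells (left) and the knockdown effect with TGF-β2 (right) against the TGF-β2 response of shGFP cells. Genes called in both comparisons are coloured: 219 in one direction and 0 opposite on the left, 38 in one direction and 2 opposite on the right.

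The interaction asks whether TGF-β2 changed a gene by a different amount under knockdown. In limma, 0 genes were called (lowest Benjamini-Hochberg adjusted p = 0.454), with 729 genes at an unadjusted p under 0.05. HSPA5 went from 377 ± 9.29 to 438 ± 28.3 TPM with TGF-β2 in shGFP cells and from 446 ± 13.6 to 706 ± 52.3 TPM in shNogo-B cells (interaction 0.44, SE 0.08, adjusted p = 0.454). ELN went from 259 ± 10.1 to 452 ± 18.9 TPM and from 196 ± 19.0 to 244 ± 12.4 TPM (−0.49, adjusted p = 0.454). Without shNogo-B control replicate 2, CIDECP1 alone was called (−3.12, adjusted p = 0.0430).

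As groups, 3 lists differed between the TGF-β2 responses, and none kept its call with an estimated correlation. Unfolded protein response genes rose more under knockdown, with 17 of 22 positive, a median interaction of 0.20, and 8 up adjusted over the list alone (camera adjusted p = 4.05e-07; adjusted p = 0.304 with an estimated correlation). BMP and SMAD1/5 targets were lower, with 11 of 13 negative, a median of −0.11, and 1 down adjusted over the list alone (camera adjusted p = 0.00140; adjusted p = 0.357 with an estimated correlation). ID1, a transcriptional regulator induced by BMP, went from 267 ± 17.2 to 231 ± 20.9 TPM in shGFP cells and from 302 ± 14.4 to 212 ± 8.91 TPM in shNogo-B cells. Mitochondrially encoded genes were higher, with 11 of 13 positive, a median of 0.07, and 2 up adjusted over the list alone (camera adjusted p = 0.00391; adjusted p = 0.845 with an estimated correlation). This last call was also lost without shGFP control replicate 1 or shGFP TGF-β2 replicate 2 (highest adjusted p = 0.564), with median-of-ratios scaling and in limma without trend. No single member of these lists was called over all genes. EndMT markers and SMAD2/3 targets were not called for the interaction (adjusted p = 0.770 and 0.780). Hepatocyte markers were lower in the interaction (median −0.35; camera adjusted p = 3.25e-10; adjusted p = 0.139 with an estimated correlation), with a median of −0.22 without shNogo-B control replicate 1.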

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

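The tests of shared libraries, of members that vary together and of RNA from another cell type, the hepatocyte marker covariate and list, and the averaged comparisons, were chosen after the results were seen. The others were fixed earlier. In 3 lists the TGF-β2 response differed between shNogo-B and shGFP cells by the interaction test with the preset correlation, and each is given here because of that difference between groups. These are unfolded protein response genes (camera adjusted p = 4.05e-07, 17 of 22 positive), BMP and SMAD1/5 targets (adjusted p = 0.00140, 11 of 13 negative) and mitochondrially encoded genes (adjusted p = 0.00391, 11 of 13 positive). With an estimated correlation none of these kept its call (adjusted p = 0.304, 0.357 and 0.845).

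The 6 libraries of a comparison of 2 groups split into 3 and 3 in 10 ways, too few for a share under 0.05, and for each comparison only 1 split, the real one, gave as many genes. For TGF-β2 in shGFP cells, the real split gave 362 genes and the highest other 3. The values were 358 and 1 for TGF-β2 in shNogo-B cells, 106 and 0 for knockdown without TGF-β2, and 113 and 0 for knockdown with TGF-β2. For the averaged effects, which use all 12 libraries, 1 of 100 drawn relabellings, the real one, gave as many genes. This argued against chance there, with 328 genes for knockdown against a highest other of 5, and 899 for TGF-β2 against 6. It did not exclude chance, since these comparisons were chosen after the data were seen. Relabellings that mix the groups also add the real differences to the spread, which lowers their counts. For the interaction the count was 0 in limma (729 genes at an unadjusted p under 0.05), so all 100 relabellings gave as many by construction, and this says nothing about chance. The highest gave 328, since that relabelling measures the averaged knockdown effect.

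Knockdown moved 38 genes of the TGF-β2 response further in the TGF-β2 direction and 2 back. Most of the 362 genes of that response were not called for knockdown with TGF-β2 in either direction. The use of the shGFP TGF-β2 libraries in both comparisons predicts a negative covariance across genes, and the measured covariance lay above the simulated mean by 0.00653, outside the simulated range. The simulated genes were independent, so that range is too narrow for genes that vary together, and this test cannot exclude the shared libraries. Scaling between libraries (36 genes with median-of-ratios scaling) and any one library (18 genes at the lowest, without shGFP TGF-β2 replicate 1) were argued against as the whole source. With the hepatocyte marker covariate 1 gene was left, all 38 kept their sign, and their median SE rose from 0.07 to 0.14. The mean marker level nearly follows the compared groups. It was 4.31 to 4.55 in the shGFP TGF-β2 libraries and 3.82 to 3.84 in the shNogo-B TGF-β2 libraries. This fit therefore cannot separate the marker level from the knockdown, and neither the lost calls nor the kept signs decide between them. A shared effect of knockdown and TGF-β2 on these genes is an open hypothesis that these tests did not reach, and an effect of the shRNA on other transcripts also stays open.

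With the preset correlation, the larger rise of unfolded protein response genes under knockdown kept its call without any one library (highest camera adjusted p = 0.000326). The call was kept with median-of-ratios scaling too (adjusted p = 5.10e-07). These checks argue against one library and scaling as its source only at that preset. Members that vary together between replicates may account for the list's call, which was lost with an estimated correlation (adjusted p = 0.304). For the interaction, no member was called over all genes, and 8 were up adjusted over the list alone. That explanation and a biological effect of Nogo-B loss on the stress response, which was not tested apart from it, both stay open.

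Hepatocyte transcripts were lower with knockdown under TGF-β2. Neither scaling between libraries (adjusted p = 2.64e-24 with median-of-ratios scaling) nor any one library (highest adjusted p = 3.92e-19) accounts for this. RNA from another cell type may be the source. All 19 markers fell, with log2 fold changes from −0.89 to −0.37. Their spread around a common factor of 0.671 was within their error (Cochran's Q, chi-square test that treats markers as independent, p = 0.905). Markers that vary together or are regulated together could pass this test too, so it does not favour RNA from another cell type over a change in these cells. ALB, FGB and FGA, among the most abundant of the list, stood at 65.04, 92.7 and 57.7 TPM with knockdown and TGF-β2, and the labels name no sort that would remove such RNA. Whether it came from cells in culture or from other RNA handled with the libraries was not tested, and a change in these cells' own transcription was not tested apart from it.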

How the results depend on the processing

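The hepatocyte marker covariate, removal of LINC01766, the reticulon list without RTN4, the averaged comparisons and the count of genes moved further were chosen after the results were seen, and the other settings before. Of 243 called gene results, 104 kept their call under each setting run on them, apart from a log2 fold change of 1 or more and leaving out a library, and 153 kept it without any single library. Of 49 called lists, 8 kept their call under each such setting and 39 without any single library. No call turned direction (0 reversed). Unless said otherwise, the cause was not tested.

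Limma without trend gave 203 genes for TGF-β2 in shGFP cells, 228 in shNogo-B cells, 29 for knockdown without TGF-β2, 57 with it, 215 for averaged knockdown and 21 genes moved further. A fit to the compared groups alone gave 189 for TGF-β2 in shNogo-B cells and 36 for knockdown without TGF-β2. At a log2 fold change of 1 or more, by construction, the counts were 36, 40, 17 and 23, then 15 for averaged knockdown, 33 for averaged TGF-β2, 3 moved further and 1 moved back. With the replicate block, knockdown gave 54 genes without TGF-β2 and 71 with it, 22 moved further and 1 moved back. In the pairing check, 3 of 12 libraries correlated best with their own replicate number.

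With the hepatocyte marker covariate, 47 genes were called for TGF-β2 in shNogo-B cells, 40 for knockdown without TGF-β2, 5 with it, 21 for averaged knockdown and 366 for averaged TGF-β2. One gene (1) moved further and 1 moved back. With it, 4 lists were called for knockdown with TGF-β2, one of them (antigen presentation) not called without it, and 7 for averaged knockdown. The correlations became 0.211 for TGF-β2 responses and 0.454 for knockdown effects, which says nothing about agreement, since this fit ties both effects of a pair to a shared coefficient. The marker level differs between the groups, so the SE rises with it.

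The correlation of TGF-β2 responses was 0.224 with a pseudocount of 0.1, 0.283 with 0.5, 0.303 with no filter and 0.465 at a mean TPM of 5 or more. That of knockdown effects was 0.166, 0.206 and 0.288 with the pseudocounts and the mean TPM of 5. Low genes are noisier, which may lower both. Genes moved back were 4 at a mean TPM of 5 or more and 5 with array weights. At that mean TPM, 13 lists were called for knockdown with TGF-β2. With an estimated correlation, lists fixed beforehand fell to 3 and 5 for TGF-β2 in shGFP and shNogo-B cells, and to 0 for knockdown without TGF-β2, with it, the interaction and averaged knockdown.

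Leaving out one library gave 213 to 372 genes for TGF-β2 in shGFP cells, 204 to 345 in shNogo-B cells, 31 to 109 for knockdown without TGF-β2, 50 to 123 with it, 0 to 1 for the interaction, 18 to 39 moved further and 1 to 3 moved back. The correlation was 0.275 to 0.312 for TGF-β2 responses and 0.183 to 0.226 for knockdown effects.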

Other observations

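The tests in this part were all chosen after the data were seen. Averaged over both treatments, knockdown changed 328 genes in limma, 196 up and 132 down, of which 174 were called in neither single comparison. The count was 215 in limma without trend and 21 with the hepatocyte marker covariate. Hepatocyte markers were lower in this average (19 of 19 negative, 8 called, median −0.40; camera adjusted p = 1.58e-18; adjusted p = 0.0352 with an estimated correlation). Epithelial markers were called down as well (adjusted p = 0.0280; adjusted p = 0.0594 with an estimated correlation). HAPLN1, which links hyaluronan to proteoglycans in matrix, stood at 2.38 ± 1.46 and 4.99 ± 0.402 TPM in shGFP cells without and with TGF-β2 and at 6.002 ± 1.78 and 12.3 ± 1.55 TPM in shNogo-B cells (averaged change 1.13, limma Benjamini-Hochberg adjusted p = 0.00621). NPR3, the clearance receptor of natriuretic peptides, stood at 6.23 ± 0.658 and 10.3 ± 1.57 TPM and at 3.18 ± 0.809 and 5.75 ± 0.217 TPM (−0.77, adjusted p = 0.00344). HAPLN1 and NPR3 both lost their call with the hepatocyte marker covariate.

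Averaged over both shRNAs, TGF-β2 changed 899 genes, 462 up and 437 down, of which 434 were called in neither single comparison. The count was 366 with the hepatocyte marker covariate. Hepatocyte markers (camera adjusted p = 3.93e-05; adjusted p = 0.151 with an estimated correlation) and epithelial markers (adjusted p = 0.000787; adjusted p = 0.0203 with an estimated correlation) were lower in this average. For hepatocyte markers, the median change with TGF-β2 was −0.03 in shGFP cells (camera adjusted p = 0.795) and −0.39 in shNogo-B cells. Of 29 proliferation genes, 15 fell in this average and 0 rose, with 22 down adjusted over the list alone. Of 22 unfolded protein response genes, 9 rose, with 12 up adjusted over the list alone. For averaged knockdown, 7 of 17 matrix proteases and inhibitors rose and 1 fell, and 7 of 28 SMAD2/3 targets rose and 2 fell.

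LINC01766 (chromosome 19, 35597907 to 35601501) was the most abundant gene, with 2.28% to 4.14% of the TPM of a library, and whether reads of another abundant transcript were counted to it was not tested. It was not called for averaged knockdown (−0.19, adjusted p = 0.538). The first principal component of the tested genes held 16.9% of the variance and ordered the groups as shGFP control, shNogo-B control, shGFP TGF-β2 and shNogo-B TGF-β2, with no overlap.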
